A study of Mus musculus with 6 samples.

How the data were processed

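Lung buds were dissected from mouse embryos at embryonic day 11.5, and total RNA was extracted with a column kit, per the labels. From each sample, 100 ng of total RNA was reverse transcribed from an oligo(dT) primer, amplified by in vitro transcription, labelled with biotin and hybridised to an Affymetrix MoGene 1.1 ST array, per the labels. One group, called control here, carried the Shhcre allele alone. The other group, called DKO here, carried Shhcre together with floxed alleles of both Hdac1 and Hdac2. Each group had 3 arrays, which the labels call biological replicates, and the stated strain background was a mixture of C57BL/6 with 129X1 and 129S1. The labels do not say whether a sample was 1 embryo or a pool, so the p-values measure the spread between these samples and not necessarily between embryos. The samples were assigned to groups by their titles.

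The deposited table held 1 log2 expression value for each of 35556 probe sets (called probes here) on each of the 6 arrays, and no further columns of per-sample values. The submitters' processing notes name oligo, RMA and limma, with no version and no settings, and RMA corrects background, makes the intensity distributions of the arrays alike and summarises the probes of a transcript on a log2 scale. The table itself does not state the log base. Base 2 was taken from the RMA method and from the range of the deposited values, which ran from 3.42 to 14.27. The array medians lay between 7.86 and 7.89, so any change in total RNA content common to all genes cannot be seen in these values. Scanner files were not used here, and the precision was limited by the number of arrays.

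Probes were named from the platform annotation. It lists 1 gene for 21789 probes and several genes for 1621 probes, and 12146 probes were unnamed here. Names were updated through Entrez identifiers against a RefSeq table of assembly GRCm38.p6, which matched 19856 genes and left 82 with their platform name. The update changed 0 symbols. For the 999 genes with several probes of their own, the probe with the highest mean over all 6 arrays was used, which left 19938 genes. No coordinates are given, because the sources used here name no genome build for the probes.

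Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided) on the deposited log2 values, with group as the only term. The p-values were adjusted by the Benjamini-Hochberg method over the 19938 genes, and an adjusted p under 0.05 was the threshold. Changes are log2 values of DKO minus control with the standard error (SE) from limma, and intervals are 95% confidence intervals. On simulated data with the spread of these arrays (5 runs on 19938 genes, 200 of them changed in each run), the test recovered 36.4% of genes changed 1.25-fold, 84.0% of those changed 1.5-fold, 99.2% of those changed 2-fold and 100% of those changed 3-fold. False calls made up 3.37% of the calls in these runs. The simulated noise was normal, independent between genes and equal in both groups. The real DKO arrays scattered more widely than the controls, so these rates may not hold for the real data.

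The 33 gene lists (cell type markers, signalling pathways, complexes and stress programmes), the groups, the tests, the threshold and all alternatives but 1 were fixed before the data were examined. The lists and a further list of sex-linked genes, which was not tested as a set, had 582 entries, of which 541 were measured by a probe with 1 gene. The lists were tested against all other genes with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 33 lists. The same test with the correlation estimated for each list is given beside it, and fry, which asks whether the members of a list moved one way on balance without comparing them with other genes, was run as an alternative. Counts of members past the threshold are given over all genes, and also adjusted over the list alone.

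The genes named in the text followed a rule: Hdac1 and Hdac2; the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose DKO and control values did not overlap, leaving out predicted and clone names, olfactory and vomeronasal receptors, small RNAs and genes of X inactivation or the Y chromosome; up to 4 members of each list past the threshold, over all genes and then over the list alone, or up to 3 members with the largest change where none passed; and Bmp4, Sox2, Rb1, Cdkn1a, Cdkn2a, Sox9, Nkx2-1 and Shh, known from the study. Cdkn1a had no probe of its own and was not analysed here. Members outside this rule are named where they complete a small count, and were chosen after their values were seen, as were the gene families among the closing observations.

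The alternatives were the replicate number as a block, an intensity trend or robust settings in eBayes, array weights, a second quantile normalization, centring each array on its median, leaving out the dimmest 30% or 50% of probes, all probes without collapsing to genes, the mean over the probes of a gene, other thresholds, ordinary least squares per gene, other set tests, and leaving out each array in turn. The mean level of the Y-linked genes as a covariate was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.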

Results

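Gene expression was measured in 6 samples of whole lung buds from mouse embryos at E11.5, when the buds begin to branch. Shhcre expresses Cre recombinase from the locus of Sonic hedgehog, which is active in the lung epithelium, and Hdac1 and Hdac2 encode closely related histone deacetylases that repress transcription within larger complexes. The 3 control samples carried Shhcre alone, and the 3 DKO samples carried Shhcre with floxed alleles of both genes. The comparison asked which genes depend on Hdac1 and Hdac2 in the developing lung. Epithelium, mesenchyme, vessels and blood were measured together, so a change in 1 cell type is diluted by the others. The arrays correlated with each other at r of 0.995 to 0.999 over all genes. The DKO arrays scattered more widely around their group mean, with standard deviations of 0.0867, 0.105 and 0.0705 on the log2 scale for DKO 1, 2 and 3, than the control arrays, with 0.0605, 0.0645 and 0.0596.

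Of the targeted genes, Hdac1 was lower in the DKO buds and Hdac2 was not detectably changed. The log2 level of Hdac1 (probe 10516605) was 11.48, 11.49 and 11.52 in controls 1 to 3, with an SD of 0.02. It was 11.21, 11.23 and 11.23 in DKO 1 to 3, with a mean of 11.22 ± 0.02 (SD, n = 3). The log2 change was -0.28 (SE 0.05, interval -0.38 to -0.17, adjusted p = 0.0193), which is 1.21-fold lower. A further Hdac1 probe gave a change of -0.26. The level of Hdac2 (probe 10362520) was 11.78 ± 0.08 (SD, n = 3) in control and 11.74 ± 0.03 (SD, n = 3) in DKO, a change of -0.04 (SE 0.06, interval -0.17 to 0.08, adjusted p = 0.845). Single control values of Hdac2 were 11.83, 11.69 and 11.81, and single DKO values were 11.74, 11.77 and 11.70. Whether these probes lie in the deleted exons was not determined here, and a probe outside the deleted part would not check the genotype. The Hdac1 call was lost without control 1, 2 or 3 (adjusted p = 0.0883, 0.0932 and 0.112), without DKO 1 (0.0517) or DKO 3 (0.0643), over all probes (0.0644), with the replicate block (0.0507) and with ordinary least squares (0.0560), at changes of -0.29 to -0.26. Among all 16 histone deacetylases and sirtuins measured, 0 rose and Hdac1 was the 1 that fell. The count adjusted over the list alone was the same (adjusted p = 0.767 for the list, and 0.915 with an estimated correlation). Of 21 members of the NuRD, Sin3 and CoREST complexes, through which Hdac1 and Hdac2 act, limma called 0 over all genes and 0 adjusted over the list alone. An unadjusted p under 0.05 was found for 3 of them (adjusted p = 0.151 for the list, and 0.724 with an estimated correlation). The largest values there were -0.24 for Sap30, -0.21 for the histone demethylase Kdm1a and -0.16 for Mbd3.

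**Figure D1:**
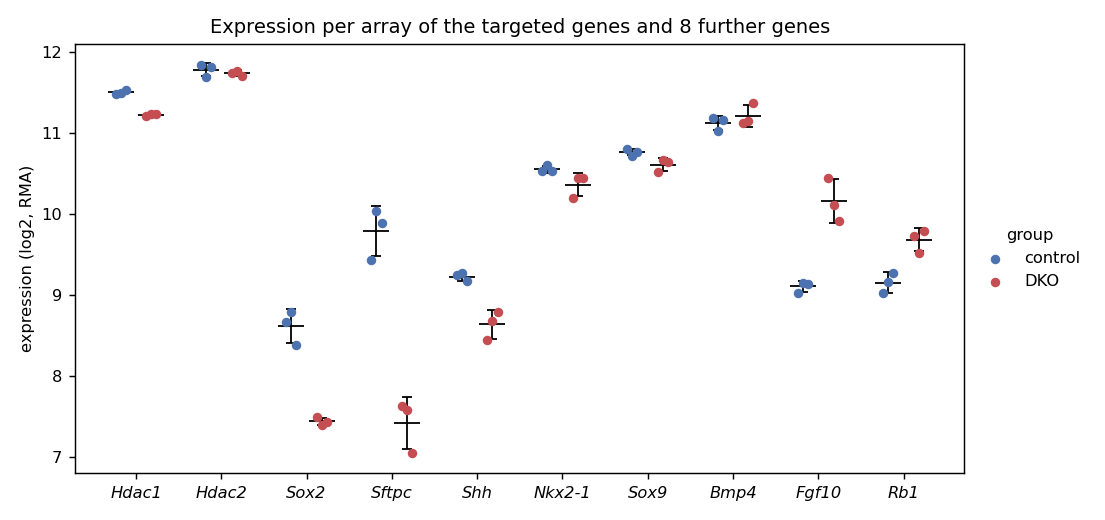
Expression (log2, RMA) of Hdac1, Hdac2 and 8 further genes on each array, with control in blue and DKO in red; horizontal bars are group means and whiskers are 1 SD (n = 3 per group). Sox2, Sftpc and Shh were lower and Fgf10 and Rb1 higher on all 3 DKO arrays, while the means of Hdac2 and Bmp4 differed by -0.04 and 0.09.

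Sftpc, Cldn18 and Sox2 were among the genes with the largest falls in the DKO buds, and Slc2a3 and Fgf10 among those with the largest rises. Sftpc, which encodes surfactant protein C of the distal epithelium, fell 5.18-fold (log2 change -2.37, SE 0.18, n = 3 per group, adjusted p = 0.000354). Cldn18, a tight junction gene of lung and stomach epithelium, fell 3.42-fold (-1.77, SE 0.07, adjusted p = 1.11e-05), and Sox2, a transcription factor of the proximal airway, fell 2.26-fold (-1.17, SE 0.09, adjusted p = 0.000545). The largest fall was 5.55-fold, in the aldehyde dehydrogenase gene Aldh1a7 (-2.47, SE 0.07, adjusted p = 8.71e-07). The largest rise was 2.82-fold, in the glucose transporter gene Slc2a3 (1.5, SE 0.06, adjusted p = 1.11e-05), and Fgf10, the mesenchymal growth factor that drives budding, rose 2.07-fold (1.05, SE 0.12, adjusted p = 0.00236). In all, 481 of 19938 genes passed the threshold, 206 higher and 275 lower in DKO. On every one of these 481 genes the 3 DKO values lay beyond the 3 control values, which passing the threshold nearly requires with 3 arrays per group. Over all genes the values were separate for 18.8%, against the 10% that chance gives. The changes were mostly modest, with 35 rises and 69 falls of at least 1.5-fold and 8 rises and 13 falls of at least 2-fold. Several probes were available for 25 of the 481 genes, and all probes of the gene changed in the same direction for 18 of these 25. For the rest, at least 1 other probe pointed the other way.

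Further genes with large falls were Cckar, a cholecystokinin receptor (-1.47), the unconventional myosin Myo5c (-1.35) and Ttc6 (-1.30). They also included the regulators of G protein signalling Rgs4 (-1.24) and Rgs5 (-1.05), the carboxylesterase Ces1d (-1.18), the zinc finger gene Zfp979 (-1.13) and Fam83b (-1.07), with SEs of 0.06 to 0.19. The rises included Calb2, which encodes the calcium-binding protein calretinin (1.28), the chemokine Cxcl15 (1.19), Gas6, a ligand of TAM receptors (1.08), Nup62cl (1.06), Rfx6, a transcription factor of pancreatic and gut endocrine cells (1.03) and Nlrp5-ps (1.03). Smaller rises were found for Alb, the albumin gene of liver (0.96), Calcrl, a receptor subunit for adrenomedullin (0.92), Dram1 (0.85) and Sftpa1, which encodes surfactant protein A (0.83). The SEs of these rises were 0.05 to 0.22. Sftpa1 thus moved opposite to Sftpc. Of these 24 genes with the largest changes, 19 stayed past the threshold whichever array was left out. Calls were lost for Calb2 and Sftpa1 without control 1, 2 or 3 (adjusted p = 0.0540 to 0.0982), for Alb without control 1, 2 or 3 or DKO 1 (0.0516 to 0.136), for Zfp979 without control 1 or 3 or DKO 3 (0.0593 to 0.10) and for Rfx6 without control 2 (0.0528). Rfx6 lies among the 200 nearest measured genes of Hdac2, which held 12 calls. The count of 481 became 215, 197 and 215 without control 1, 2 and 3, 811 without DKO 2, and 317 without DKO 3.

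**Figure D2:**
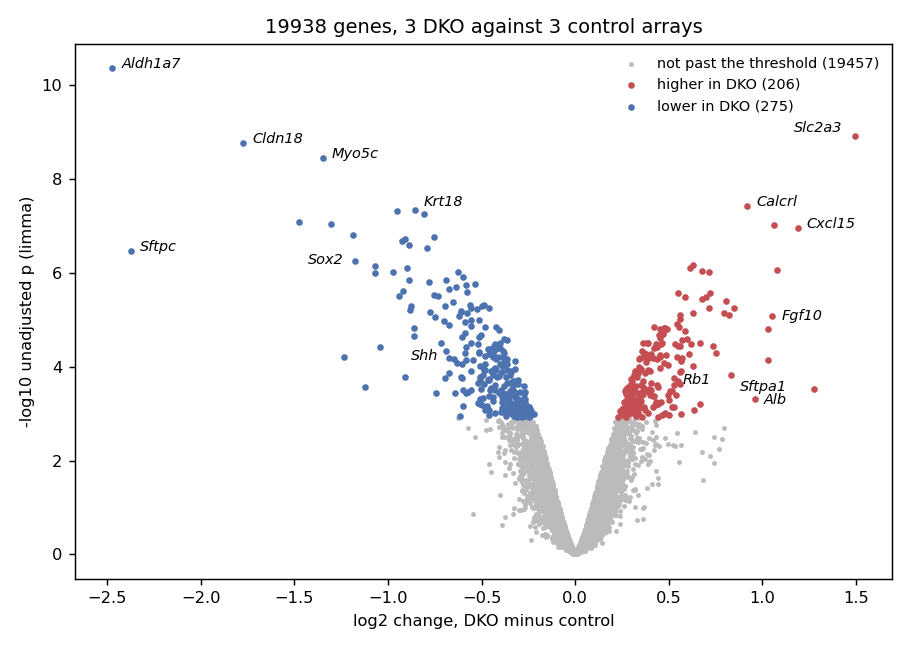
Each point is 1 of 19938 genes; the x axis is the log2 change, DKO minus control, and the y axis is -log10 of the unadjusted p from limma. The 206 genes higher in DKO are red and the 275 lower are blue, and the falls of Aldh1a7 (-2.47) and Sftpc (-2.37) reach farther than the largest rise (Slc2a3, 1.5).

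Most genes shared by the whole lung epithelium fell, and their list passed with the preset correlation (adjusted p = 1.07e-25) but not with an estimated correlation (adjusted p = 0.190). Of 25 measured markers, 14 fell and 0 rose, and 22 fell when adjusted over the list alone. The strongest were the epithelial trafficking gene Rab25 (-0.89, SE 0.06, n = 3 per group, 1.85-fold lower), the keratin gene Krt18 (-0.86, SE 0.05, 1.81-fold lower) and the transcription factors Foxa1 (-0.69, SE 0.07, 1.62-fold lower) and Grhl2 (-0.61, SE 0.07, 1.53-fold lower). The lung determinant Nkx2-1 did not pass (-0.19, SE 0.07, adjusted p = 0.299). The median over the list was -0.34 and the mean -0.39. The count of 14 became 8 without control 2 and 9 without control 3. Of 14 markers of the distal epithelium, 2 fell and 1 rose. Sftpc and Etv5, a target of FGF signalling, fell (Etv5 -0.34, SE 0.07, adjusted p = 0.0366). The carboxypeptidase gene Cpm rose (0.48, SE 0.07, adjusted p = 0.00740). Adjusted over the list alone, 6 fell and 2 rose, with a median of -0.13 and a mean of -0.22 (adjusted p = 0.0119, and adjusted p = 0.450 with an estimated correlation). The distal progenitor factor Sox9 (-0.15, SE 0.06, adjusted p = 0.281) and Bmp4, a BMP ligand of the bud tips (0.09, SE 0.08, adjusted p = 0.733), did not pass, and Wnt7b stood at -0.31 (adjusted p = 0.0859, and 0.0154 without DKO 2). Of 16 markers of the proximal airway, Sox2 and Tppp3 (-0.42, SE 0.06, adjusted p = 0.00790) fell and 0 rose, the same count as adjusted over the list alone. This list did not pass (adjusted p = 0.655, and 0.849 with an estimated correlation), and its median of 0.02 and mean of -0.08 differ in sign. The distal list lost its call without control 1 (adjusted p = 0.0541), with array weights (0.0503), without the dimmest 30% (0.0549) or 50% (0.167) of probes and with camera on ranks (0.0769), and the count of 3 became 2 without each array but DKO 2. Etv5 lost its call without control 1, 2 or 3, DKO 1 or DKO 3 (0.0646 to 0.171), and Tppp3 lost it without control 1 (0.0527) or control 3 (0.0501).

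**Figure D3:**
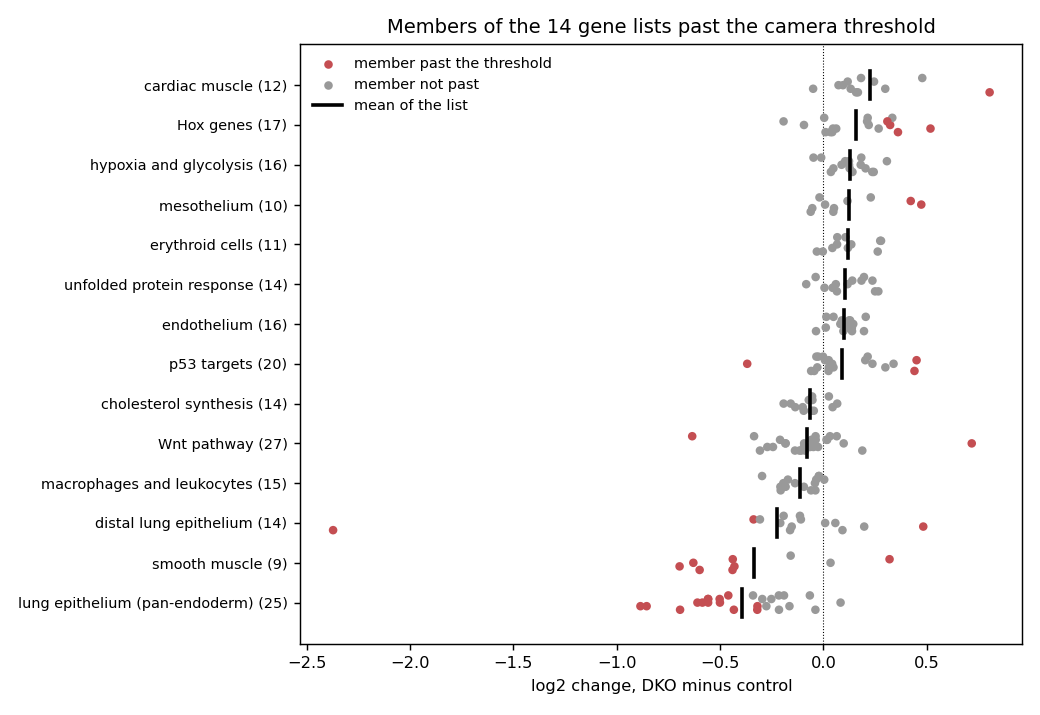
Log2 changes, DKO minus control, of the members of the 14 gene lists past the camera threshold, with the number of measured members in brackets. Red points are genes past the threshold on their own, grey points are not, and black bars are list means, from 0.22 for cardiac muscle to -0.39 for lung epithelium.

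The sonic hedgehog ligand and its feedback inhibitor fell, and 3 of 4 FGF receptors fell and the ligand Fgf10 rose. Shh, secreted by the epithelium, fell 1.5-fold (-0.59, SE 0.08, n = 3 per group, adjusted p = 0.00813) and Hhip, a hedgehog antagonist in the mesenchyme, also fell 1.5-fold (-0.58, SE 0.11, adjusted p = 0.0240). They were the 2 of 13 hedgehog pathway genes that fell, with 0 rising over all genes. When adjusted over the list alone, 2 fell and 1 rose, the latter being Gli3 (0.16). The hedgehog list did not pass (adjusted p = 0.282, and 0.504 with an estimated correlation). Of 18 FGF pathway genes, Fgf10 rose and 4 fell: Fgfr2, the epithelial receptor for Fgf10 (-0.58, SE 0.06, 1.5-fold lower), Fgfr4 (-0.46, SE 0.06), Etv5 and Fgfr3 (-0.32, SE 0.05). Fgfr1 did not pass (0.04, SE 0.06, adjusted p = 0.862). Shh is also on the lung epithelium list, and Fgfr2 is an epithelial receptor. For both, a lower share of epithelial cells and lower expression within them cannot be told apart here. Once adjusted over the list alone, 3 rose and 6 fell. The FGF list had a median of 0.03, a mean of 0.00 that was below 0 before rounding, and a test pointing down (adjusted p = 0.770, and 0.915 with an estimated correlation). Shh lost its call without control 2 (adjusted p = 0.0532), Hhip without control 2 or 3 or DKO 1 (0.0609 to 0.120), and the FGF count of 5 became 3 without control 1 or 2.

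Of the other signalling pathways, the Wnt list passed with the preset correlation, the BMP, Notch and retinoic acid lists did not, and none passed with an estimated correlation (adjusted p = 0.450 to 0.804, with 0.450 for both Wnt and retinoic acid). Of 27 Wnt pathway genes, the secreted inhibitor Dkk1 rose 1.64-fold (0.72, SE 0.07, n = 3 per group, adjusted p = 0.00128) and Rnf43, a membrane ubiquitin ligase that is itself a Wnt target, fell 1.55-fold (-0.64, SE 0.06, adjusted p = 0.00106). The ligands Wnt5a (-0.34, adjusted p = 0.0960) and Wnt7b (-0.31, adjusted p = 0.0859) did not pass, although Wnt5a did without DKO 1 (0.0144) and Wnt7b without DKO 2 (0.0154). With p-values adjusted over the list alone, 6 Wnt genes fell and 1 rose, with a median of -0.09 and a mean of -0.08 (adjusted p = 0.00139, and adjusted p = 0.450 with an estimated correlation). Of 24 BMP pathway genes, 1 rose, the pseudoreceptor Bambi (0.31, SE 0.05, adjusted p = 0.0167), and 0 fell, which was also the count adjusted over the list alone (adjusted p = 0.655 for the list, and 0.804 with an estimated correlation). Of 17 Notch pathway genes, the target Hes1 (-0.30, SE 0.05, adjusted p = 0.0184) and the glycosyltransferase Lfng (-0.30, SE 0.06, adjusted p = 0.0305) fell and 0 rose, the same count as adjusted over the list alone (adjusted p = 0.282 for the list, and 0.504 with an estimated correlation). Of 12 retinoic acid pathway genes, limma called 0 over all genes, against 5 with an unadjusted p under 0.05. Adjusted over the list alone, 4 fell, which were Stra6 (-0.30), Crabp1 (-0.22), Rarb (-0.20) and Rarg (-0.19), and 1 rose (adjusted p = 0.174 for the list, and 0.450 with an estimated correlation). Without control 1, 2 or 3 the calls of Bambi (adjusted p = 0.0529 to 0.0996) and Hes1 (0.0757 to 0.106) were lost, and that of Lfng was lost without any of the controls, DKO 1 or DKO 3 (0.0824 to 0.144).

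Smooth muscle genes fell while most of the mesenchymal genes did not pass. Of 9 smooth muscle genes, 6 fell and 1 rose. The largest falls were in the enteric actin gene Actg2 (-0.70, SE 0.11, n = 3 per group, 1.62-fold lower), calponin Cnn1 (-0.63, SE 0.09, 1.55-fold lower), the myosin heavy chain gene Myh11 (-0.60, SE 0.12, 1.51-fold lower) and Acta2 (-0.44, SE 0.08, 1.36-fold lower). Tagln (-0.44, SE 0.08) and the coactivator Myocd (-0.43, SE 0.07) also fell, and desmin, Des, rose (0.32, SE 0.06). When adjusted over the list alone, 7 fell and 1 rose, with a median of -0.44 and a mean of -0.34 (adjusted p = 1.65e-05, and adjusted p = 0.141 with an estimated correlation). The single calls were unstable: the count of 7 became 2 without control 1, 0 without control 2 or control 3 and 3 without DKO 3. Where their calls were lost, the adjusted p was 0.0530 and 0.0547 for Cnn1 and 0.0570 to 0.152 for Actg2, Myh11 and Acta2, with changes of Acta2 between -0.49 and -0.37. Of 20 mesenchymal genes, Fgf10 and the homeobox gene Meox2 (0.63, SE 0.05, adjusted p = 0.000646) rose and Twist2 fell (-0.28, SE 0.06, adjusted p = 0.0395). Once adjusted over the list alone, 3 rose and 2 fell, with Wnt2, a mesenchymal Wnt ligand, at -0.27 (adjusted p = 0.104 over all genes). This list had a median of -0.04, a mean of 0.04 and a test pointing down (adjusted p = 0.890, and 0.927 with an estimated correlation). Of 10 mesothelial genes, 2 rose and 0 fell, Upk1b (0.47, SE 0.07, adjusted p = 0.00904) and Gpm6a (0.42, SE 0.08, adjusted p = 0.0260). There were 3 rises when adjusted over the list alone, with Lrrn4 at 0.23. The mesothelial median was 0.05 and the mean 0.12 (adjusted p = 0.0199, and adjusted p = 0.450 with an estimated correlation). That call was lost without control 2 (adjusted p = 0.0555), without DKO 3 (0.195) and with camera on ranks (0.143). Twist2 and Gpm6a lost theirs without any of the controls or DKO 3 (0.0505 to 0.186), Twist2 also without DKO 1 (0.0969).

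The cardiac, endothelial, erythroid and leukocyte lists passed with the preset correlation, the lists of neural crest and of stomach, liver and thyroid did not, and none passed with an estimated correlation (adjusted p = 0.141 to 0.818). Of 12 cardiac muscle genes, 1 rose and 0 fell: Myl7, the atrial myosin light chain gene, rose 1.75-fold (0.80, SE 0.08, n = 3 per group, adjusted p = 0.00163). With p-values adjusted over the list alone, 6 rose, including Myl4 (0.48), Tnnt2 (0.30) and Myl2 (0.24). The cardiac median was 0.16 and the mean 0.22 (adjusted p = 6.74e-06, and adjusted p = 0.141 with an estimated correlation). For 16 endothelial genes limma called 0, against 2 with an unadjusted p under 0.05, and 0 when adjusted over the list alone. Yet 15 of the 16 values were above 0, among them Tek (0.20), Cdh5 (0.20) and Sox17 (0.14). The endothelial list passed with a median of 0.11 and a mean of 0.10 (adjusted p = 0.00163, and adjusted p = 0.450 with an estimated correlation). Of 11 erythroid genes, 0 passed over all genes, against 3 with an unadjusted p under 0.05. The gene count was 2 rises when adjusted over the list alone, with Gata1 at 0.27 and the embryonic globin gene Hbb-bh1 at 0.26. The erythroid median was 0.11 and the mean 0.12 (adjusted p = 0.00472, and adjusted p = 0.504 with an estimated correlation). Of 15 macrophage and leukocyte genes, 0 passed over all genes, against 5 with an unadjusted p under 0.05. There were 3 falls when adjusted over the list alone, in Tyrobp (-0.30), Csf1r (-0.21) and Laptm5 (-0.21). The median of that list was -0.09 and its mean -0.11 (adjusted p = 0.00103, and adjusted p = 0.190 with an estimated correlation). Of 11 markers of neural crest and neurons, the migration gene Dcx rose (0.38, SE 0.05, adjusted p = 0.00724) and the neuregulin receptor gene Erbb3, which is also expressed in epithelia, fell (-0.88, SE 0.09, adjusted p = 0.00199). Adjusted over the list alone, 1 rose and 2 fell, with Ret at -0.28 (adjusted p = 0.309 for the list, and 0.818 with an estimated correlation). Of 11 genes of the stomach, liver and thyroid, 1 rose, Alb, and 0 fell. There were 2 rises when adjusted over the list alone, with the other liver gene Afp at 0.53 (adjusted p = 0.0680 for the list, and 0.672 with an estimated correlation). The endothelial call was lost without DKO 1 (adjusted p = 0.159) and with array weights (mean 0.04, adjusted p = 0.230). The erythroid call was lost without control 1 (0.0541) and without the dimmest 50% of probes (0.167). The list of stomach, liver and thyroid passed without DKO 1 (0.0288) or DKO 3 (0.0275) and with the replicate block (0.0357). Afp also passed over all genes with that block (adjusted p = 0.0165). The list of neural crest and neurons passed without DKO 3 (0.0291). Without DKO 2, 3 cardiac genes passed over all genes, with Myl4 at 0.57 and Tnnt2 at 0.38.

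No shift of proliferation genes was detected, and the cell cycle brake Rb1 rose. Rb1, which encodes the retinoblastoma protein, rose 1.44-fold (0.53, SE 0.09, n = 3 per group, adjusted p = 0.0149). It was the 1 of 9 genes for CDK inhibitors and the Rb family that rose, with 0 falling, and adjusted over the list alone 1 rose and 1 fell, the latter being Cdkn1c (-0.23, adjusted p = 0.106 over all genes). That list did not pass (adjusted p = 0.767, and 0.849 with an estimated correlation), and Cdkn2a was at -0.14 (SE 0.08, adjusted p = 0.531). For 25 genes of DNA replication, limma called 0 over all genes, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. The largest values were 0.14 for Pola1, -0.12 for Cdc6 and -0.10 for Slbp (adjusted p = 0.291 for the list, and 0.804 with an estimated correlation). For 24 genes of mitosis, 0 passed over all genes and 0 adjusted over the list alone, against 3 at an unadjusted p under 0.05. The values included Ccnb2 at 0.15, Ttk at 0.14 and Prc1 at -0.13 (adjusted p = 0.765 for the list, and 0.915 with an estimated correlation). Of 20 p53 targets, 2 rose, cyclin G1 Ccng1 (0.45, SE 0.05, adjusted p = 0.00354) and the desmosomal gene Perp (0.44, SE 0.09, adjusted p = 0.0346). The 1 that fell was the antiproliferative gene Btg2 (-0.37, SE 0.07, adjusted p = 0.0250). When adjusted over the list alone, 5 rose and 1 fell, with Tnfrsf10b at 0.34. The p53 median was 0.03 and the mean 0.09 (adjusted p = 0.0242, and adjusted p = 0.261 with an estimated correlation). The p53 list lost its call without control 1 (adjusted p = 0.0553) or DKO 1 (0.0528), without the dimmest 30% (0.138) or 50% (0.210) of probes and with camera on ranks (0.143). Perp lies among the 200 nearest measured genes of Hdac2. The calls were also lost for Rb1 without control 1 or 2 or DKO 3 (0.0581 to 0.0737), Perp without any of the controls or DKO 1 (0.0671 to 0.157) and Btg2 without control 1 or 2 or DKO 3 (0.0769 to 0.128).

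Among programmes kept silent or limited by chromatin in other settings, the Hox list passed upwards with the preset correlation (adjusted p = 1.61e-05) but not with an estimated correlation (adjusted p = 0.141), and no shift of germline or neuronal genes was detected. Of 17 Hox genes, which encode positional transcription factors, 4 rose and 0 fell: Hoxb1 (0.52, SE 0.09, n = 3 per group, 1.43-fold), Hoxb5 (0.36, SE 0.07), Hoxa4 (0.32, SE 0.06) and Hoxb3 (0.31, SE 0.06). Once adjusted over the list alone, 9 rose, with a median of 0.21 and a mean of 0.16. The control means of Hoxb1 (8.57), Hoxa4 (10.44) and Hoxb3 (10.83) lay above the highest array median of 7.89, as did that of Hoxb5. These 4 genes were therefore not silent in the control buds. Since all cell types were measured together, a lower epithelial share and higher expression cannot be told apart for the Hox list. Of 19 germline genes, the meiotic gene Sycp2 rose (0.28, SE 0.06, adjusted p = 0.0431) and 0 fell, which was also the count adjusted over the list alone. The germline list had a median of -0.02, a mean of 0.00 that was above 0 before rounding, and a test pointing down (adjusted p = 0.890, and 0.927 with an estimated correlation). Of 25 neuronal genes bound by the repressor REST, 1 rose, Chga, which encodes chromogranin A (0.44, SE 0.06, adjusted p = 0.00796), and 0 fell. With p-values adjusted over the list alone 3 rose, with Snap25 at 0.32 and Gad1 at 0.26. Both lists rest largely on dim probes: without the dimmest 30% of probes 3 of 19 germline and 20 of 25 REST genes were left, of which 0 and 3 rose, and without the dimmest 50% 1 and 3 were left, of which 0 passed. The REST list had a median of -0.02, a mean of 0.02 and a test pointing up (adjusted p = 0.765, and 0.915 with an estimated correlation). Of 8 genes known to rise under HDAC inhibitors, H1f0 and Cdkn1a had no probe of their own and were not tested. Of the 6 measured, Clu fell (-0.42, SE 0.05, adjusted p = 0.00338) and 0 rose. Adjusted over the list alone, 3 of them rose and 3 fell, with the metallothioneins Mt2 at 0.27 and Mt1 at 0.19 and Txnip at 0.21. The inhibitor list had a median of 0.03, a mean of 0.00 that was below 0 before rounding, and a test pointing down (adjusted p = 0.890, and 0.927 with an estimated correlation). The count of 4 Hox genes became 0 without control 1, 2 or 3 (adjusted p = 0.0836 to 0.154) and 1 without DKO 3, and Hoxb5 also lost its call without DKO 1 (0.0516). Sycp2 lost its call without any of the controls or DKO 3 (0.108 to 0.196), and Snap25 passed without DKO 1 (0.0392) or DKO 2 (0.0340).

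The lists of hypoxia, the unfolded protein response and cholesterol synthesis passed with the preset correlation, the immediate early and ribosomal lists did not, and none passed with an estimated correlation (adjusted p = 0.294 to 0.849). For 16 genes of hypoxia and glycolysis, limma called 0 over all genes and 0 adjusted over the list alone, against 8 with an unadjusted p under 0.05. Of these 16 values 14 were above 0, with Bnip3 at 0.31 (SE 0.13, n = 3 per group), Egln3 at 0.24 (SE 0.07) and P4ha1 at 0.24 (SE 0.08). A further Bnip3 probe gave 0.17. The hypoxia list passed with a median of 0.13 and a mean of 0.13 (adjusted p = 2.01e-05, and adjusted p = 0.434 with an estimated correlation). Of 14 genes of the unfolded protein response, 0 passed over all genes, against 5 with an unadjusted p under 0.05. There were 4 rises when adjusted over the list alone: Asns (0.27), Creld2 (0.24), Pdia4 (0.20, with a further probe at 0.004) and Xbp1 (0.18). That list had a median of 0.09 and a mean of 0.11 (adjusted p = 0.00170, and adjusted p = 0.294 with an estimated correlation). For 14 genes of cholesterol synthesis, 0 passed over all genes and 0 adjusted over the list alone, against 3 with an unadjusted p under 0.05. The largest values were Nsdhl at -0.19, Insig1 at -0.16 and Dhcr7 at -0.14. Its median was -0.06 and its mean -0.06 (adjusted p = 0.0457, and adjusted p = 0.457 with an estimated correlation). Of 14 immediate early and heat shock genes, the AP-1 subunit Jun fell 1.47-fold (-0.56, SE 0.06, adjusted p = 0.00193) and 0 rose. When adjusted over the list alone 1 fell and 1 rose, the latter being Ier3 (0.21). The immediate early list did not pass (adjusted p = 0.637, and 0.849 with an estimated correlation). Of 16 ribosomal protein genes, 1 fell and 0 rose, which was also the count adjusted over the list alone. This was Rps9 (-0.25, SE 0.05, adjusted p = 0.0371), whose other probe gave 0.08. The ribosomal list did not pass (adjusted p = 0.283, and 0.743 with an estimated correlation). The cholesterol call was lost without control 1 (adjusted p = 0.0689), control 3 (0.0934), DKO 1 (0.232) or DKO 2 (0.159). It was also lost with array weights (0.428), a second quantile normalization (0.0568) and without the dimmest 30% (0.102) or 50% (0.140) of probes. The ribosomal list passed without DKO 1 (0.0320), and Rps9 lost its call without any of the controls, DKO 1 or DKO 3 (0.0822 to 0.186). Without DKO 2, Bnip3 (0.46, adjusted p = 0.0186) and P4ha1 (0.32, adjusted p = 0.0182) passed over all genes.

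Across the 33 lists, 14 passed with the preset correlation, 8 upwards and 6 downwards, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.141 and 6 lists had an unadjusted p under 0.05. With fry, 5 lists passed, which were lung epithelium, smooth muscle, cardiac muscle, Hox genes and p53 targets.

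No difference of the sex-linked genes between the groups was detected. Xist, transcribed from the inactive X chromosome, was at 12.16 ± 0.39 (SD, n = 3) in control and 12.11 ± 0.34 (SD, n = 3) in DKO, and the Y-linked gene Eif2s3y was at 10.17 ± 0.44 (SD, n = 3) and 10.16 ± 0.32 (SD, n = 3). Of the 4 sex-linked genes measured, Xist, Kdm5d, Eif2s3y and Uty, 0 passed over all genes in limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, with changes of -0.05, -0.01, -0.01 and -0.08. The arrays differed within each group. Control 3 and DKO 1 had the lowest Xist (11.74 and 11.75) and the highest Eif2s3y (10.65 and 10.53), and control 2 had the highest Xist (12.52) and the lowest Eif2s3y (9.79). Both genes thus lay above the highest array median of 7.89 on every array. A single embryo of either sex would not carry both signals at such levels, so these values argue against samples of 1 embryo each. How many embryos a sample held is not known.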

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

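The tests of the 481 genes and 14 lists by other splits of the arrays were planned, and the choice of the 4 unnamed probes described here was made after their values were seen. Probes that were not used for any gene also differed between the groups, which stood out as signal outside the measurements compared above. When all probes were tested together, 37 of the 12146 probes unnamed here passed the threshold, 17 higher and 20 lower in DKO. Of the 1621 probes listed for several genes, 19 passed, 5 higher and 14 lower. Probe 10582896 fell 21.0-fold (log2 change -4.39, SE 0.56, adjusted p = 0.0373), a larger change than that of any named gene. Its controls were at 11.63, 9.88 and 11.21 and its DKO arrays at 7.45, 5.81 and 6.29. Probe 10582916 fell 12.4-fold (-3.63, SE 0.47, adjusted p = 0.0400). Probe 10340994 rose 4.74-fold (2.24, SE 0.22, adjusted p = 0.0189) and probe 10398354 rose 2.49-fold (1.31, SE 0.06, adjusted p = 0.000841). On each of these 4 probes the DKO values lay beyond the control values on all arrays, and no explanation was tested for them.

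The 6 arrays can be split into groups of 3 in 10 ways, so no count of splits can reach a share under 0.05. The real split gave 481 genes past the threshold, 1 of the 10 splits gave as many, and the highest of the others gave 0. The real split gave 14 lists, and 2 of the 10 splits gave as many. The other one set controls 1 and 3 with DKO 3 against the remaining arrays, and 14 was also the highest count among the other splits. With camera at the preset correlation, the smallest adjusted p of a list was 1.07e-25 in the real split, for lung epithelium, and 2.18e-05 among the others. The hypoxia list, at 2.01e-05 in the real split, was nearly matched in another. It had an adjusted p of 2.46e-05 where control 1, DKO 1 and DKO 3 were set against the rest. With an estimated correlation the lung epithelium list did not pass in the real split (adjusted p = 0.190). The other split with 14 lists called 0 genes. Like every split but the real one, it holds 2 controls on one side and 1 on the other. A difference between the genotypes then adds to the spread within both sides and lowers the gene count. The contrast of 481 with 0 is therefore no comparison with data free of a genotype difference.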

How the results depend on the processing

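The mean level of the Y-linked genes as a covariate was chosen after the data were seen, and the other alternatives were planned. With it 395 genes (166 and 229) and 14 lists passed, and Etv5, Twist2, Myh11, Perp, Hoxb3, Sycp2 and Rps9 lost their call (adjusted p = 0.0513 to 0.0714). The 65 named genes past the threshold kept their call in 652 of 761 cases over 12 refitted alternatives. None changed sign, but this tests nothing. Several alternatives leave the log2 change as it was, and the genes were picked for passing. Of the 109 lost calls, 59 of 65 came with ordinary least squares and 34 of 65 when all probes were tested. With the cut at 1.5-fold 37 of the 65 stayed. Named genes below the threshold gained a call in 81 of 638 cases, including 36 of 54 with array weights and 17 of 54 with an intensity trend. Hdac1 lost its call at the same change of -0.28 with all probes (adjusted p = 0.0644), with the replicate block (0.0507) and with ordinary least squares (0.0560), over a range of 0.00135 to 0.112 in these 12 and the 6 fits without 1 array. The count of 481 genes (206 higher, 275 lower) became 725 (337 higher) with an intensity trend, 2003 (1006 and 997) with array weights, 208 (82 and 126) with all probes, 740 (330 higher) at an adjusted p under 0.10, and 16 (4 and 12) with ordinary least squares. At 1.5-fold or more it was 104 (35 and 69), and 114 (44 and 70) with the p unadjusted. All 481 were among the 2003. The array weights were 0.275 for DKO 2 and 4.09 for DKO 3. The count was 603 and 567 without the dimmest 30% and 50% of probes. For all these shifts the cause was not tested. Leaving out 1 array gave 197 to 811 genes (83 to 385 higher, 112 to 426 lower), with Hdac1 at -0.29 to -0.26. Named genes below the threshold gained a call in 16 of 324 fits without 1 array, 13 of them without DKO 2, and named genes past it lost theirs in 98 of 390. With the replicate block 406 genes passed, 358 of them shared with the 481, and 8 of the 65 named genes lost their call while Afp gained a call. Same-numbered arrays deviated together by r of -0.06, 0.05 and 0.16, and 3 of the 6 arrays correlated best with their own number, so the numbers were not taken as pairs. The 14 lists became 0 with estimated correlations and 5 with fry, and 10 to 15 otherwise. Lists below the threshold had another direction in 28 of 379 alternatives, in 10 of 19 lists. Signal over background was not analysed here, so how far dim probes understate a change is open.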

Other observations

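The tests of cell composition, carried-over heart tissue and chromosomal neighbours in this part, like the gene families, were chosen after the results were seen. Class 3 semaphorins, secreted guidance cues of nerves and vessels, moved in both directions. Of 7 measured, Sema3c (0.63, SE 0.07, 1.55-fold), Sema3d (0.56, SE 0.08, 1.48-fold) and Sema3a (0.47, SE 0.06, 1.38-fold) rose and Sema3e fell (-0.68, SE 0.06, 1.60-fold lower), with n = 3 per group and an adjusted p of 0.00115 to 0.00824. All 4 lie among the 200 nearest measured genes of Shh, the locus that carries Cre in both groups, which held 8 calls (15.9% of windows of 200 genes had as many), against 1 among its 100 nearest (84.8%). Of 11 semaphorin receptor genes, Plxnc1 rose (0.36, SE 0.06, adjusted p = 0.0239). Of 21 Eph receptors and ephrins, Efna3 (0.68, SE 0.06) and Epha3 (0.42, SE 0.05) rose and Efna1 fell (-0.25, SE 0.05).

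Some claudins, keratins and 1 mucin fell, and Cldn4, Cldn6, Krt8 and Krt18 are also on the lung epithelium list. No enrichment of these families was tested. Of 23 claudins, which form tight junctions, 5 fell and 0 rose: Cldn18, Cldn6 (-0.56, SE 0.09), Cldn4 (-0.56, SE 0.07), Cldn10 (-0.55, SE 0.08) and Cldn1 (-0.45, SE 0.07), while the median of the family was -0.01. Of 48 keratins, the simple epithelial keratins Krt18, Krt7 (-0.61, SE 0.10) and Krt8 (-0.56, SE 0.06) fell and 0 rose, while the median was 0.01. The mucin Muc1 fell 1.96-fold (-0.97, SE 0.08, adjusted p = 0.000661), the 1 call among 12 mucins, whose median was -0.01. Aldh1a1, which lies in the same gene family as Aldh1a7, fell 1.71-fold (-0.78, SE 0.08, adjusted p = 0.00211). Of 20 regulators of G protein signalling, 3 fell (Rgs4, Rgs5 and Rgs6) and 2 rose (Rgs2 and Rgs18). The platelet gene Ppbp (0.57, SE 0.07, adjusted p = 0.00513) and the blood progenitor gene Hemgn (0.60, SE 0.08, adjusted p = 0.00494) rose.

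The fall of epithelial genes may come from a lower share of epithelial cells in the DKO buds, from lower expression within them, or from both. The 25 members differed by more than their SEs (chi-square test of heterogeneity, p = 1.28e-63), from Rab25 at -0.89 to Krt19 at 0.08, the 1 of 25 above 0, but probes differ in response and some members are also expressed outside the epithelium, so unequal falls decide nothing. Smooth muscle genes, which are not epithelial, had a mean of -0.34 (SE 0.06). A lower epithelial share by itself would raise them, so the value argues against the shift in shares itself as the cause of that fall. Whether fewer epithelial cells lowered these genes by another route was not tested. The means of other lists that are not epithelial were above 0 for cardiac muscle (0.22), mesothelium (0.12), erythroid cells (0.12) and endothelium (0.10), the direction a lower share would bring, and below 0 for leukocytes (-0.11) and neural crest (-0.09), while mesenchyme had a mean of 0.04 and a median of -0.04. The neural crest list, with a median of -0.08, includes Erbb3 (-0.88), which is also expressed in epithelia and pulls its mean down. The Hox list, which shares Hoxa5 with the mesenchyme list, had a mean of 0.16. A lower epithelial share would bring this direction too if the Hox genes are expressed mainly outside the epithelium, which was not tested. Sox2 and Sftpc fell beyond the list mean by -1.38 (SE 0.17), but this pair was chosen after its large falls were seen. Sox2 was also among the genes named as known from the study, and at -1.17 it fell farther than Rab25. Since probes differ in response, this decides nothing either. For the lung epithelium list, Sox2 and Sftpc, a lower share and lower expression within the epithelium cannot be told apart, since no cells were counted here.

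The rise of the cardiac list may reflect heart tissue carried over in the dissections, or expression in the buds themselves. Heart tissue would bring its abundant transcripts together, and the median linear difference of the 11 other members was 5.18% of that of Myl7, at most 6.61% without any 1 array. However, 3 of the 11, Myl4 (59.3%), Tnnt2 (42.9%) and Actc1 (34.7%), differed by 25% of it or more, and probes differ in response, so carry-over and expression in the buds cannot be told apart. The linear differences of Myh6, Myh7 and Nppa, which are abundant in heart, were 3.42%, 3.06% and 2.11% of that of Myl7.

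The strain background was mixed, so variants of 129X1, 129S1 or C57BL/6 origin linked to a floxed allele could change probe signals or expression near Hdac1 and Hdac2. Among the 100 nearest measured genes of Hdac1 there was 1 call, against a median of 2 in windows of 100 genes, and 84.8% of the windows had as many, an ordinary count that leaves an effect on single genes such as Tmem54, the 1 called, open. Among the 100 nearest of Hdac2 there were 5 calls, Ddo, Fig4, Ppil6, Armc2 and Mtres1, and 12.1% of the windows had as many. With 50 neighbours there was 1 call (64.3% of windows) and with 200 there were 12 (1.86%), including Rfx6 and Perp, so linked variants near Hdac2 stay open for these genes too.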
